A study of Rattus norvegicus with 12 samples.

How the data were processed

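Liver tissue of Sprague-Dawley rats was measured on 12 Affymetrix Rat Genome 230 2.0 arrays, which carry 31099 probe sets, 57 of them controls. Per the labels' protocols, tissue was taken from the right lobe, at its middle, total RNA was extracted with Trizol and purified with RNeasy, and biotin-labelled cRNA was hybridised. Per the submitters' processing notes, the program was GCOS 2.0; its summarization settings are not stated. Groups were taken from the labels: normal liver at 0h and liver at 3, 6 and 9 weeks of the carbon tetrachloride model, with 3 arrays each. The labels call the arrays of a group technical replicates and do not give the number or sex of the animals.

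Per the file headers, the deposited workbook holds 1 intensity (signal) column per array, on a linear scale and scaled by the authors: the mean of each column after trimming 2% from each end was 500.2 in all 12 arrays. The series table deposited beside it holds the same intensity values, within 0.1. The authors' workbook also holds 9 columns of log2 ratios against 0h for each time, in steps of 0.1, whose method is not stated. These ratios were used only as a comparison: their mean per gene correlated with the changes computed here at r = 0.945, 0.97 and 0.969 across genes, which are not independent replicates. Every per-sample column was matched to its label, so the number left unmatched is 0. Detection calls are not in the files.

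Signals were used as log2(signal + 16) and not renormalized, because the array medians lay between 7.09 and 7.31 on that scale. Arrays give no counts, so the precision stated is that between arrays, which their number limits. It does not cover differences between animals. Within groups, arrays correlated at r = 0.967 to 0.977 across probe sets, and between groups at 0.937 to 0.969. A probe set was kept when its mean over the 12 arrays was above the 40th percentile of all probe sets, a log2 value of 6.513 or a signal of 75.3, which left 18625. Symbols were brought up to date with a RefSeq gene table of the rat: 15165 probe sets had a current symbol, 2960 were updated through a synonym and 244 through their accession. A further 13 without a symbol were named through their accession, and 1516 kept the symbol in the file. Probe sets without a symbol (11121), with several (23) and controls were left out of the gene tests. The brightest kept probe set stood for its gene, which gave 10321 genes. Genome positions were not used here.

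All 12 arrays were fitted as 4 group means with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 8 residual degrees of freedom and a median residual SD of 0.131 log2 units. Each of the 3 times was compared with 0h, and 6 weeks with 3 weeks and 9 weeks with 6 weeks, 5 comparisons in all. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested and a change of at least 2-fold. A moderated F test over the 3 comparisons with 0h, with at least 1 change of 2-fold, gave the genes that changed over the course. Overlaps of calls were set beside 100 simulations of unchanged groups, drawn with the spread between arrays and tested against a shared simulated 0h group. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

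The comparisons, thresholds, filter, 22 gene lists, rule for named genes and most alternatives were chosen before the data were examined. The rule names, for each time against 0h, the 6 largest rises and 6 largest falls among called genes, and in each list the called member with the largest change. For the steps between times it names the 5 largest rises and 5 largest falls. Locus and clone names do not qualify. Members of the lists, and genes that rose at 1 time and fell at another, may be given with their values as well. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Lists with under 5 measured genes were described and not tested. The lists cover matrix proteins, matrix proteases, stellate cells, P450 enzymes, phase II enzymes, bile acids, fatty acid oxidation and synthesis, cholesterol synthesis, urea cycle with amino acid and glucose metabolism, plasma proteins, acute phase proteins, cell cycle, macrophages, lymphocytes, MHC class II, chemokines, bile duct cells, endothelium, stress genes, red cells with granulocytes, and neighbouring tissues. List members without a value were below the filter or not analysed here. A further 11 lists were written once the data were in hand (male-biased, female-biased, Y-linked, clock activators, clock repressors and outputs, interferon-induced, erythroid, ribosomal, mitochondrial, amino acid response and endoplasmic reticulum genes), and those of female-biased genes, clock repressors, interferon-induced and amino acid response genes leave out genes already seen. The male-biased list holds the falls that prompted it, and all 5 measured erythroid genes are also in the list of red cells with granulocytes, so no p is given for these 2 lists.

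The method was tested on simulated data, with 50 genes changed by a known fold in arrays set up as a 9 week and 0h comparison. It called 0% of genes changed 1.5-fold, 54% at 2-fold, 100% at 3-fold and 100% at 4-fold, with 3 false calls. The shares at 1.5-fold and 2-fold follow largely from the 2-fold minimum. The shifted list was called, and 0 of 20 unshifted lists. Genes were simulated independently, whereas the estimated correlation within the list of plasma proteins was 0.599. The list result therefore cannot tell how often camera calls an unshifted list of correlated genes. The alternatives were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization and median centring, the mean of a gene's probe sets and every probe set on its own. Others were eBayes without the trend, a fit of only the 6 arrays compared, the other deposited table, the replicate number as a block, adjusted p under 0.01, no fold minimum, at least 3-fold, and leaving out each array. Whole times left out of the time course were added after seeing the data.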

Results

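Expression was measured in liver tissue of Sprague-Dawley rats on 12 Affymetrix Rat Genome 230 2.0 arrays. The arrays fell into 4 groups of 3: normal liver at 0h, and liver at 3, 6 and 9 weeks of a cirrhosis model made with carbon tetrachloride, a solvent that hepatocytes turn into a reactive radical that injures them. The labels call the 3 arrays of a group technical replicates, and the number of animals is not given in the sources used here, so the p-values measure the spread between arrays only. Normal liver at 0h was the only control; no group given vehicle alone or matched in time was among the samples. An array signal has no count behind it, so the number of arrays limits the precision between arrays. Differences between animals are not covered by it. Signals are in the authors' scaled units and are given as mean ± SD (n = 3 arrays per group). Changes are in log2(signal + 16) units, with their SE where one is given; this scale understates the change of genes near or below 75.3, the signal level of the filter. A gene is said to rise or fall when its limma p, adjusted by Benjamini-Hochberg over the 10321 genes tested, was under 0.05 and the change was at least 2-fold. Among the genes so called, the largest adjusted p was 0.0479 at 3 weeks, 0.0458 at 6 weeks and 0.0444 at 9 weeks. The number of called members of each list adjusted over the list alone was the same as over all genes tested in all 165 pairs of list and comparison. The p given for a list is from camera, adjusted over the lists of a comparison.

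The comparison of 3 weeks with 0h asked which genes had changed early in the model. The lists of matrix and MHC class II genes were shifted up, and that of cholesterol synthesis down. Spink1, a secreted trypsin inhibitor, rose from 238 ± 55.8 to 10074 ± 516, a log2 change of 5.34 ± 0.11. A2m, a protease inhibitor that is an acute phase protein in the rat, rose from 739.6 ± 23.3 to 18865 ± 1012, a change of 4.64 ± 0.09. A1bg, a plasma glycoprotein of the liver, fell by 7.47 ± 0.11, from 25852 ± 1396 to 131.3 ± 24.3. In all, 301 genes rose and 132 fell.

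Other large rises at 3 weeks were those of Fst, an activin antagonist (3.23 ± 0.28), Tgfb1, the main profibrotic growth factor (3.21 ± 0.20), Rgs4, a regulator of G protein signalling (3.06 ± 0.34), and Abcc3, an export pump for conjugated bile acids and drugs (2.88 ± 0.24). All 4 started from dim signals at 0h, such as 13.6 ± 6.6 for Tgfb1. Large falls included those of Cpa1, a pancreatic carboxypeptidase (fell by 7.31 ± 0.35), and Obp3, of the alpha-2u globulin family (fell by 5.26 ± 0.15). Akr1b7, an aldo-keto reductase, fell by 3.19 ± 0.06. Cyp8b1, the sterol hydroxylase of bile acid synthesis, fell by 3.18 ± 0.04. Alpha-2u globulins are near-identical paralogs, so the assignment of the Obp3 signal to 1 gene is uncertain. The 3 kept probe sets of Spink1 gave 1.14, 4.89 and 5.34.

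Of 28 measured collagens and other matrix proteins, 12 rose and 1 fell at 3 weeks (adjusted p = 2.39e-08). Col1a1, a chain of type I collagen, rose by 2.24, Col3a1, of type III collagen, by 1.61, Lum, a proteoglycan that orders collagen fibrils, by 2.62 ± 0.22, and Dcn, a proteoglycan of the same kind, by 1.89. Lox, which crosslinks collagen, fell by 1.68. Among 21 stellate cell and myofibroblast markers, 2 rose (Tgfb1 and Acta2, smooth muscle actin, from 149 to 310 in mean signal) and 1 fell (adjusted p = 0.00143). Of 13 matrix proteases and inhibitors, Mmp19 rose by 1.01 ± 0.08 and the others did not pass (adjusted p = 0.0107; adjusted p = 0.0708 with an estimated correlation). The rise of Mmp19 was at the 2-fold limit: it was 0.98 without 0h replicate 3 and was also just short of 2-fold without 3 week replicate 2.

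Among 7 measured MHC class II genes, which present antigen to T cells, 5 rose, with a list median of 1.23 (adjusted p = 1.2e-06). Cd74, the invariant chain, rose by 1.56 and RT1-Bb by 1.72 ± 0.05. RT1 genes are paralogs and their probe sets differed: a second RT1-Bb probe set gave 4.22, and those of RT1-Ba gave 1.16, 2.27 and -0.09. Of 18 macrophage and Kupffer cell markers, Gpnmb, a lysosomal glycoprotein of activated macrophages, rose by 1.45 ± 0.06 (adjusted p = 0.000171). No lymphocyte marker among 16 passed (median 0.25, adjusted p = 0.364). Among 24 chemokines, cytokines and adhesion molecules, 6 rose and Cxcl14 fell by 1.60 (adjusted p = 0.0107; adjusted p = 0.128 with an estimated correlation). Ccl21, which draws in lymphocytes and dendritic cells, rose by 2.79 ± 0.11, Cxcl1, which draws in neutrophils, by 2.50, and Cxcl9 by 1.27. Of 7 red cell and granulocyte markers, S100a9, a neutrophil protein, rose by 1.11 ± 0.06 (adjusted p = 0.133), while the globins Hbb (-0.12) and Hba-a2 (-0.17) did not pass.

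Cholesterol synthesis showed the clearest fall at 3 weeks: 11 of 21 measured genes fell and none rose (median -1.11, adjusted p = 2.61e-19). Msmo1, a sterol methyl oxidase, fell by 2.28 ± 0.07 and Idi1, an isomerase of the pathway, by 2.15. Among 17 fatty acid synthesis genes, Fasn (fatty acid synthase) rose from 4551 to 9102 in mean signal, Acaca rose by 1.04, and Fads2, a desaturase, fell by 1.06 ± 0.07 (adjusted p = 0.691); without 3 week replicate 3, Fads2 changed by -0.97. Of 21 fatty acid oxidation genes, Cpt1a, which brings fatty acids into mitochondria, fell by 2.63 ± 0.08 and Pdk4 by 1.28 (adjusted p = 0.0024; adjusted p = 0.204 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.52, and with Cyp8b1 it was 1 of 2 falls among 18 bile acid genes (adjusted p = 0.0035; adjusted p = 0.128 with an estimated correlation). In the list of urea cycle, amino acid and glucose metabolism, Sds, a serine dehydratase, fell by 2.00 ± 0.07, and Asl and Hal also fell (26 measured, adjusted p = 1.96e-05; adjusted p = 0.139 with an estimated correlation).

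At 3 weeks, 6 of 27 phase II and antioxidant genes rose, among them Abcc3, Ugt2b1 (1.56), Gpx2 (1.43) and Gclc (1.14), and none fell (adjusted p = 0.0011; adjusted p = 0.0994 with an estimated correlation). Of 25 P450 genes, Cyp1a1 rose and Cyp2c12 and Cyp3a9 fell, by 1.22 ± 0.05 and 1.04 (adjusted p = 0.0298; adjusted p = 0.374 with an estimated correlation). The P450 list no longer passed without 0h replicate 2 (adjusted p = 0.0573), without 3 week replicate 1 (adjusted p = 0.0578) or with quantile normalization (adjusted p = 0.131). Among 20 acute phase genes, 5 rose (adjusted p = 0.0035; adjusted p = 0.256 with an estimated correlation): A2m, Lbp, which binds bacterial lipopolysaccharide, by 1.72, the transcription factor Cebpd by 1.44, the phospholipase Pla2g2a by 1.28, and Lcn2, an iron-siderophore binder, from 523 to 2521 in mean signal. The abundant acute phase transcripts Hp (-0.06), Orm1 (0.10) and Crp (0.07) did not pass, and neither did any of 27 plasma and coagulation proteins (median -0.04, adjusted p = 0.254; without 0h replicate 3, adjusted p = 0.0354).

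Growth and stress genes had few calls at 3 weeks. Of 35 cell cycle genes, Plk1, a mitotic kinase, fell by 1.33 ± 0.27 from a dim signal and Cdkn3 by 1.14 (adjusted p = 0.691). Among 24 stress and p53 genes, Cdkn1a, a cell cycle inhibitor, rose by 1.73 ± 0.16 and Myc rose, and Plk2 and Egr1 fell, by 1.24 and 1.14 (adjusted p = 0.321). Of 14 bile duct and progenitor cell markers, Sox4 (1.22), Dmbt1 (1.14) and Spp1 (1.07) rose, and Onecut1, a hepatocyte and duct transcription factor, fell from 5854 ± 367 to 2478 ± 147 (adjusted p = 0.0937); the second probe set of Onecut1 gave -0.54. None of 16 endothelial markers passed (adjusted p = 0.24). In the list of neighbouring tissues, 8 measured, the genes that moved were Cpa1 and Fabp4, a fatty acid carrier of fat cells and macrophages, which rose by 2.83 (adjusted p = 0.325). The share of called genes that rose, 69.5%, was 57.2% with each array centred on its median, which moved the median of all genes from 0.01 to -0.09.

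The comparison of 6 weeks with 0h asked what had changed midway in the model. Here 531 genes rose and 457 fell, and the large falls included transcripts that are abundant in normal male rat liver. Car3, carbonic anhydrase of liver and muscle, fell by 8.22 ± 0.13, from 34179 ± 2841 to 100.9 ± 30.2. Cyp2c11, the main male-specific P450, fell by 6.49 ± 0.09, from 20718 ± 708 to 215.9 ± 24.3. Acot1, a thioesterase that splits acyl-CoA, rose by 7.30 ± 0.22, from 10.2 ± 12.6 to 3845 ± 395.

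Gstm4, a glutathione transferase (4.88 ± 0.31), Chpf, which builds chondroitin chains (4.80 ± 0.19), Cyp1a1, a P450 induced through the aryl hydrocarbon receptor (4.48 ± 0.30), Phgdh, the first enzyme of serine synthesis (4.46 ± 0.14), and Spink1 (4.43 ± 0.11) were the next largest rises at 6 weeks. A1bg (-7.82 ± 0.11), Obp3 (-7.50 ± 0.15) and Cpa1 (-6.98 ± 0.35) fell. Probe sets of the Cyp2c family may be read by several genes, and the file names that of Cyp2c11 only as Cyp2c.

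Of 25 P450 genes, 3 rose and 6 fell at 6 weeks (median -0.62, adjusted p = 6.89e-06; adjusted p = 0.0967 with an estimated correlation). Besides Cyp2c11, Cyp3a9 (-3.44) and Cyp1a2, which metabolises caffeine (-3.28), fell, while Cyp1a1, Cyp4b1 (1.59) and Por, the electron donor of P450s (1.08), rose. Cyp2e1, which activates carbon tetrachloride, did not pass (-0.32). Among 27 phase II genes, 5 rose and 2 fell (adjusted p = 0.19): Abcc3 rose by 4.37 ± 0.24, Gpx2 by 3.30, Akr7a3 by 2.54 and Srxn1 by 1.85, and Sult1c3 fell by 3.26. Of 18 bile acid genes, 5 fell, among them Abcc2, a canalicular export pump, by 1.56 ± 0.06 and Slc10a1, the bile salt uptake carrier, by 1.18 (adjusted p = 0.000106; adjusted p = 0.0544 with an estimated correlation).

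Both lists of lipid synthesis were shifted down at 6 weeks. In cholesterol synthesis 16 of 21 fell and none rose (median -1.32, adjusted p = 9.58e-16), with Idi1 down to 1411 ± 57.6 from 11412 ± 281 and Hmgcs1, HMG-CoA synthase, falling by 2.48. In fatty acid synthesis 11 of 17 fell and Me1, malic enzyme, rose from 998 to 2310 in mean signal (median -1.24, adjusted p = 5.47e-06); Fads1 fell by 2.58 ± 0.08, Thrsp by 1.63 and Fasn by 1.18. Among 21 fatty acid oxidation genes, the rises were those of the thioesterases Acot1 and Acot2 (2.81), which split acyl-CoA and do not oxidise it, and Fabp1, a fatty acid carrier, fell by 1.17. The median of that list was -0.08, its mean 0.43 and its test direction up (adjusted p = 0.947). In the urea cycle and amino acid list 4 of 26 fell, among them Hal, histidine ammonia lyase (-2.54 ± 0.08), and Bhmt (-1.97) (adjusted p = 0.000651; adjusted p = 0.205 with an estimated correlation); with quantile normalization adjusted p was 0.554. Of 27 plasma proteins, 4 fell (median -0.51, adjusted p = 2.37e-11; adjusted p = 0.176 with an estimated correlation), including Igfals by 1.79 ± 0.07 and Igf1 by 1.61, while albumin (Alb) changed by -0.33 and did not pass.

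The cell cycle list was shifted up at 6 weeks. Among 35 cell cycle genes 12 rose and none fell (median 0.69, adjusted p = 0.000442): Rrm2, a ribonucleotide reductase subunit, by 1.75 ± 0.11, Ccnd1, cyclin D1, by 1.71, Top2a by 1.27 and Mki67, a proliferation marker, by 1.18. Of 24 stress genes 8 rose and Plk2 fell (adjusted p = 0.0106; adjusted p = 0.0797 with an estimated correlation). Trib3, a stress-induced pseudokinase, rose by 3.49 ± 0.09, Cdkn1a by 2.82, Myc by 2.79 and Atf3, a stress transcription factor, by 2.18. In the acute phase list Lcn2 rose by 3.86 ± 0.07 and Lbp by 1.21, and A2m (-2.62, to a signal of 107.8 ± 13.8) and Pla2g2a (-2.21) fell (20 measured, adjusted p = 0.19).

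Lymphocyte and macrophage markers were lower as lists at 6 weeks than at 0h. Of 16 lymphocyte markers 6 fell and none rose (median -0.61, adjusted p = 0.000337): the cytotoxic granule genes Gzma, by 3.16 ± 0.17, Prf1, by 2.63, and Gzmb, by 1.64, and the chemokine Ccl5, by 2.16. Among 18 macrophage markers Adgre1, Itgam and Aif1 fell, by 1.08, 1.08 and 1.18, and Gpnmb rose by 2.63 ± 0.06 (median -0.54, adjusted p = 0.000651). No MHC class II gene of 7 passed (median -0.27, adjusted p = 0.19). Of 24 chemokine and adhesion genes 4 rose, among them Tnfrsf12a (1.74), and 5 fell, with Cxcl12 falling by 2.62 ± 0.05 (adjusted p = 0.0884). The red cell and granulocyte list was also shifted down: 5 of 7 red cell and granulocyte markers fell (median -2.03, adjusted p = 5.47e-06), Hbb from 27019 to 4928 in mean signal and Ahsp, a chaperone of alpha globin, with a change of -3.27 ± 0.30. Of 16 endothelial markers 3 fell, Plvap, of vessel fenestrae, by 2.42 ± 0.34 (adjusted p = 0.0318; adjusted p = 0.0833 with an estimated correlation).

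Matrix genes had few calls at 6 weeks. Of 28 matrix genes Dcn (1.88) and Loxl1 (1.49) rose and Lox fell by 2.12 ± 0.16 (adjusted p = 0.277). Among 13 proteases 4 rose, Mmp12, a macrophage elastase, by 3.68 ± 0.28 and Plat, a plasminogen activator, by 1.68 (adjusted p = 0.126). Of 21 stellate cell markers 5 rose and 1 fell (adjusted p = 0.19), with Tgfb1 at 2.83 ± 0.20 and Ccn2, connective tissue growth factor, at 1.86. In the bile duct list Spp1, osteopontin, rose by 3.01 ± 0.13, Krt8 rose by 1.13 and Onecut1 fell by 1.86 (14 measured, adjusted p = 0.475). The second probe set of Onecut1 gave -0.96, short of 2-fold. Among neighbouring tissue genes Cpa1 and Cpb1 fell and Fabp4 rose by 3.99 (adjusted p = 0.0944).

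The comparison of 9 weeks with 0h asked what had changed by the end of the model. Here 652 genes rose and 375 fell, and the lists of MHC class II, matrix, stellate cell and bile duct genes were shifted up while those of lipid synthesis were shifted down. Acot1 rose by 7.28 ± 0.22, Spink1 by 5.11 ± 0.11, from 238 ± 55.8 to 8581 ± 421, Phgdh by 4.63 ± 0.14, Abcc3 by 4.61 ± 0.24, Chpf by 4.45 ± 0.19 and Gstm4 by 4.43 ± 0.31. Large falls were those of Obp3 (-7.39 ± 0.15), Cpa1 (-7.05 ± 0.35), A1bg (-6.72 ± 0.11), Car3 (-6.37 ± 0.13), Cyp2c11 (-6.21 ± 0.09) and Akr1b7 (-4.92 ± 0.06).

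Of 28 matrix genes 5 rose and Lox fell at 9 weeks (median 0.61, adjusted p = 0.0202): Loxl1, a crosslinking enzyme, rose by 2.31 ± 0.37 from a dim 24.1 ± 2.4, Dcn by 1.87, Col1a1 by 1.73 and Col6a2 by 1.29. Among 21 stellate cell markers 8 rose and 1 fell (median 0.84, adjusted p = 0.0127), with Tgfb1 at 3.73 ± 0.20, Ccn2 at 2.01, Tagln, a smooth muscle protein, at 1.23 and Tgfb3 at 1.13. Of 13 proteases 4 rose (adjusted p = 0.00903), Mmp12 by 3.33 ± 0.28, Plat by 1.92 and Timp1, an inhibitor of matrix proteases, by 1.35. Bile duct and progenitor cell markers rose, 6 of 14, with 1 fall (median 0.81, adjusted p = 0.00326): Cd24 by 1.73, Sox4 by 1.70, Spp1 by 1.62 and Dmbt1 by 1.56, and Onecut1 fell by 2.52 ± 0.06, its second probe set giving -1.76.

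At 9 weeks 6 of 7 MHC class II genes rose (median 1.96, adjusted p = 1.35e-05): RT1-Bb by 2.62 ± 0.05, to 9975 ± 216, RT1-Db1 by 2.06, Cd74 by 2.03 and Ciita, the activator of class II transcription, by 1.42. Probe sets of RT1 genes differed here too: the second of RT1-Bb gave 5.151, and those of RT1-Ba gave 1.962, 1.625 and 0.175. Of 24 chemokine and adhesion genes 8 rose and Cxcl12 fell (adjusted p = 0.119); Cxcl9, an interferon-gamma-induced attractant of T cells, rose by 2.19 ± 0.09, Cxcl16 by 2.07 and Ccl21 by 1.68. Among 18 macrophage markers Gpnmb (3.18 ± 0.06), Tyrobp (from 962 to 2761 in mean signal) and Lgals3, galectin 3 (1.28), rose (adjusted p = 0.125). Of 16 lymphocyte markers Gzma fell by 1.42 ± 0.17 and the others did not pass (median 0.08, adjusted p = 0.995). Red cell and granulocyte markers stayed lower, 5 of 7 (median -1.22, adjusted p = 8.2e-07): Ahsp fell by 3.33 ± 0.30, S100a9 by 1.86 and Hbb by 1.07. Of 16 endothelial markers Ramp2, a receptor partner, rose by 1.07 ± 0.10 (adjusted p = 0.247); without 0h replicate 3 it was 0.99, short of 2-fold.

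Several metabolic lists were shifted down at 9 weeks, with most of their members not called. Cholesterol synthesis had 9 falls in 21 (median -0.96, adjusted p = 2.96e-13), among them Idi1 (-2.04). Fatty acid synthesis had 8 falls in 17 (median -0.96, adjusted p = 2.64e-07): Elovl5, an elongase (-2.50 ± 0.08), Gpam (-2.28) and Elovl6 (-1.62) fell. Of 26 urea cycle and amino acid genes 6 fell, Hal by 2.85 ± 0.08, Sds by 1.69 and Otc, ornithine transcarbamylase, by 1.18 (adjusted p = 4.67e-10). Of 18 bile acid genes 4 fell, Abcc2 by 1.62 ± 0.06 and Cyp7a1 by 1.43 (adjusted p = 0.000356). Plasma proteins had 3 falls in 27, Igf1, insulin-like growth factor, by 1.39 ± 0.05, C8a by 1.17 and Igfals by 1.10 (adjusted p = 4.67e-10; adjusted p = 0.162 with an estimated correlation). Among 25 P450 genes Cyp1a1 (3.75) and Cyp4b1 (1.94) rose and Cyp2c11, Cyp1a2 and Cyp3a9 fell (adjusted p = 1.46e-06; adjusted p = 0.0604 with an estimated correlation). In fatty acid oxidation Acot1 and Acot2 rose, and Pdk4 and Fabp1 fell, by 1.64 and 1.01; the median was -0.17, the mean 0.28 and the test direction down (adjusted p = 0.213). The 2 kept probe sets of Cpt1a gave -0.26 and -1.08 at 9 weeks.

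Of 27 phase II genes 6 rose and 2 fell at 9 weeks (adjusted p = 0.0184; adjusted p = 0.162 with an estimated correlation): Abcc3, Akr1b8 (3.16), Akr7a3 (3.06), Gpx2 (3.05), Gstp1, a glutathione transferase of injured liver (2.93), and Srxn1 (2.27) rose. Cell cycle genes rose, 8 of 35 (median 0.68, adjusted p = 0.00276), with Ccnd1 at 1.82 ± 0.08 and Rrm2 at 1.43, although the second probe set of Rrm2 gave 0.24. Of 24 stress genes 7 rose and Plk2 fell (adjusted p = 0.00196), with Trib3 at 3.34 ± 0.09, Atf3 at 2.86 and Cdkn1a at 2.80. In the acute phase list Lbp and Cebpd rose by 1.14 and 1.06 and A2m fell by 1.58 ± 0.09 (20 measured, adjusted p = 0.00595; adjusted p = 0.218 with an estimated correlation; 0.566 with quantile normalization). Cpa1 and Cpb1 fell and Fabp4 rose by 3.70 among neighbouring tissue genes (adjusted p = 0.152). The 3' to 5' signal ratios of control probe sets were higher at 9 weeks than at 0h: 1.41 ± 0.02 against 1.12 ± 0.06 for Gapdh, 3.54 ± 0.28 against 2.36 ± 0.31 for beta-actin, and 3.64 ± 0.19 against 1.44 ± 0.11 for the added thr spike. The thr spike is added and is not from the tissue, so processing differed between the 9 week and 0h arrays. Its ratio was also above 0h at 3 weeks (1.91 ± 0.07) and 6 weeks (2.05 ± 0.05), while the dap spike ratio stayed near 0h there. The added poly-A spikes, thr and dap among them, were brighter than at 0h by 1.129 log2 units at 3 weeks, 1.082 at 6 weeks and 0.454 at 9 weeks. The part of processing in the changes at any of these times cannot be told apart from that of the model.

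**Figure D1:**
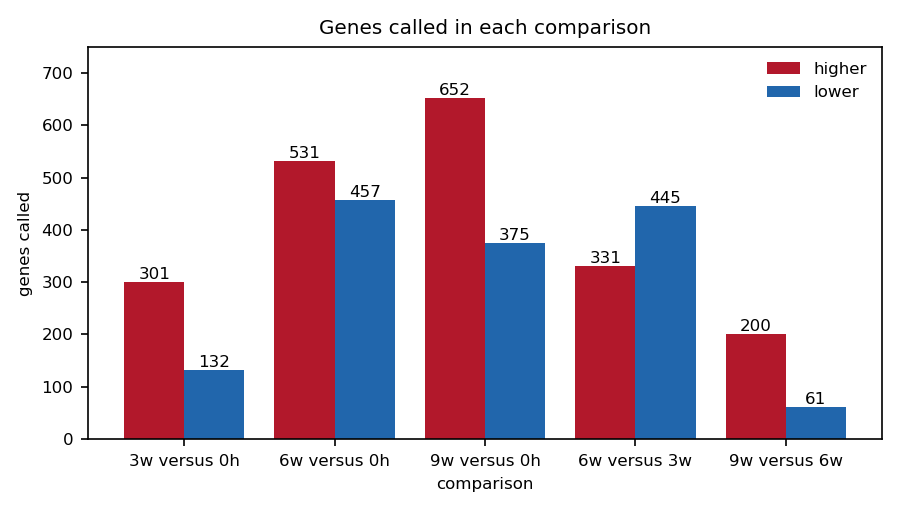
Number of genes called higher (red) and lower (blue) in each of the 5 comparisons. The counts against 0h went from 301 and 132 at 3 weeks to 652 and 375 at 9 weeks, and the step from 6 to 9 weeks had 200 rises and 61 falls.

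**Figure D2:**
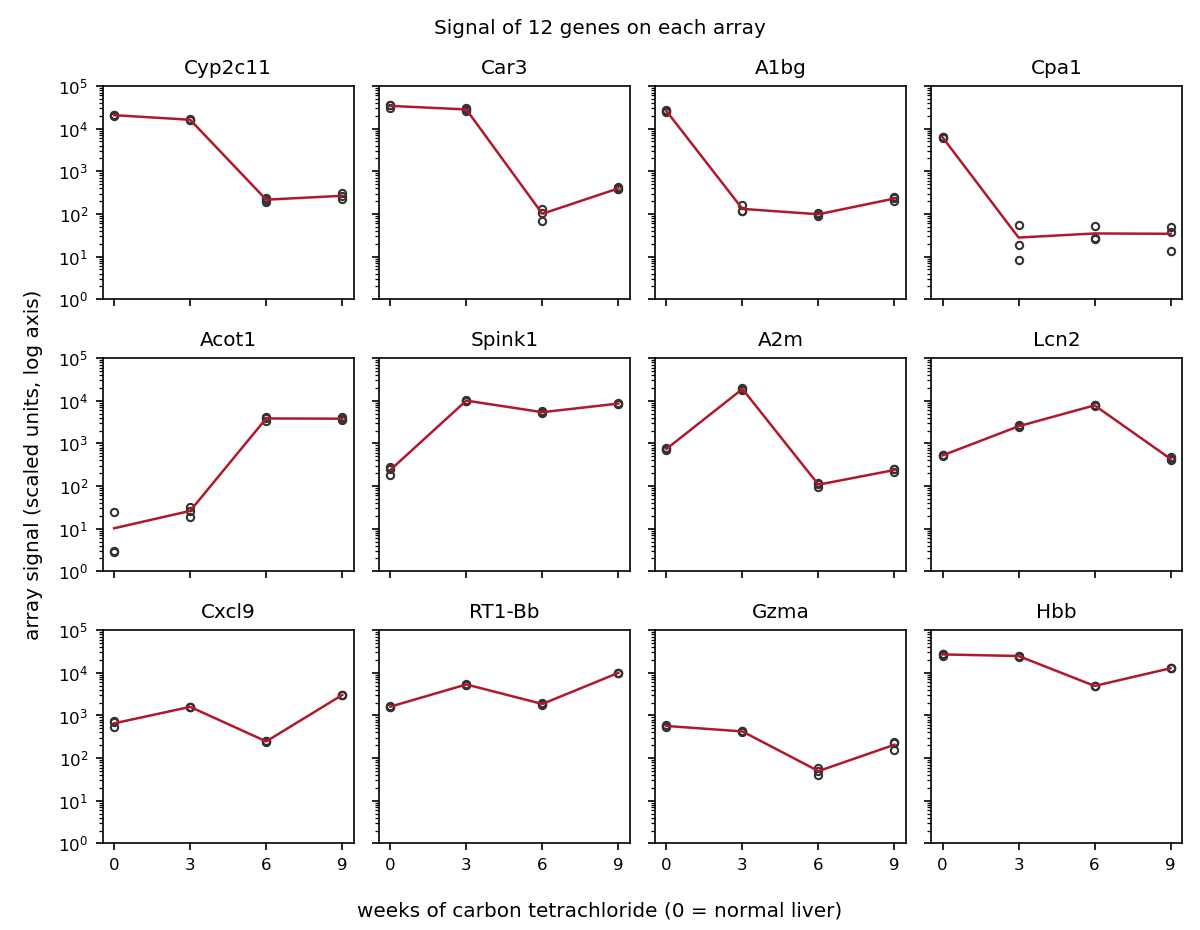
Signal of 12 genes on each of the 12 arrays (open circles, log axis, scaled units) against weeks of carbon tetrachloride, with the line through the 4 group means. The genes were picked by hand after their values were seen. Car3 and Cyp2c11 were bright at 0 and 3 weeks and dim at 6 and 9 weeks, and RT1-Bb, Cxcl9, Gzma and Hbb were dimmer at 6 weeks than at 3 and 9 weeks.

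**Figure D3:**
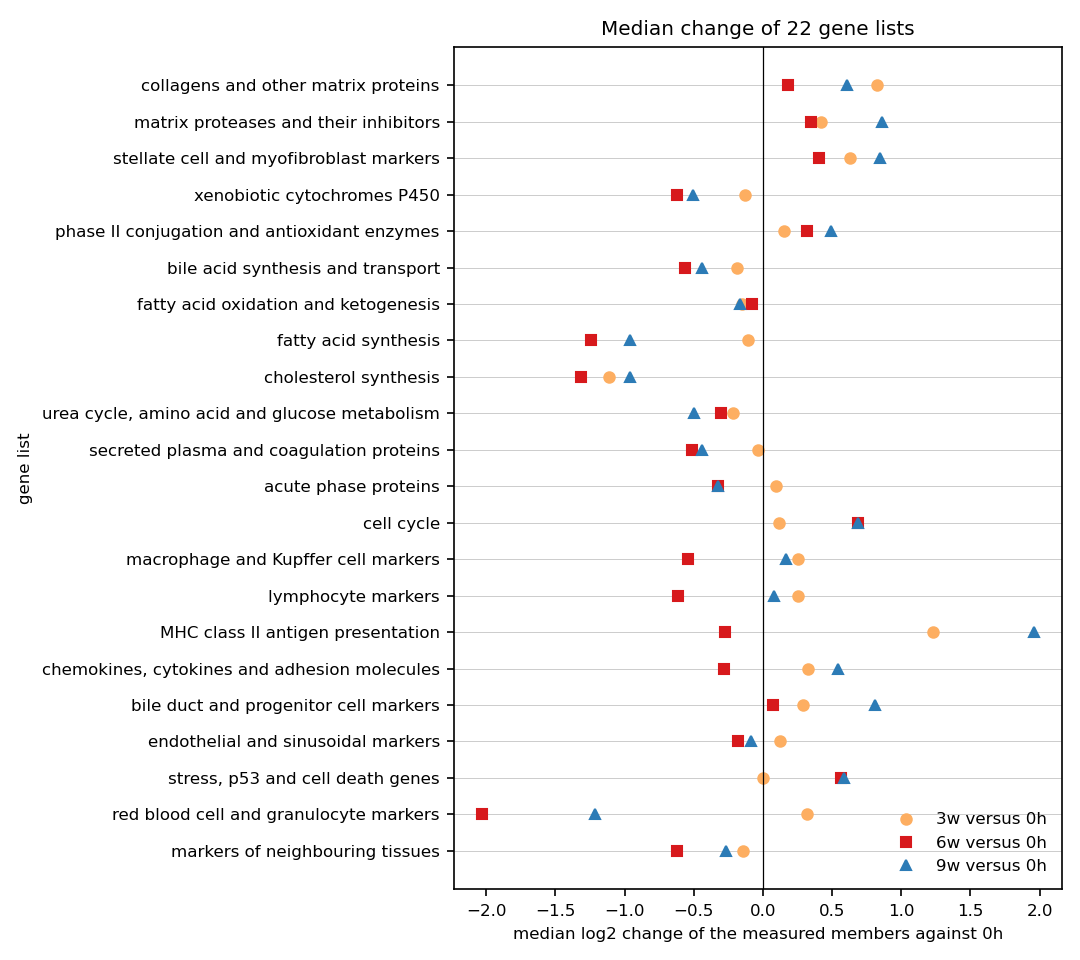
Median log2 change of the measured members of the 22 gene lists against 0h at 3 weeks (circles), 6 weeks (squares) and 9 weeks (triangles). MHC class II genes stood at 1.23, -0.27 and 1.96, and cholesterol synthesis genes at -1.11, -1.32 and -0.96.

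The step from 3 to 6 weeks asked what changed between the early and the middle stage; 331 genes rose and 445 fell. With each array centred on its median, 399 rose and 386 fell, so the excess of falls depends on the scaling. Acot1 rose by 6.53 ± 0.22, Trib3 by 3.77 ± 0.09, Abcb1, a drug export pump, by 3.70 ± 0.09, Cyp1a1 by 3.39 ± 0.30 and Gstm4 by 3.09 ± 0.31. A2m fell by 7.26 ± 0.09, from 18865 ± 1012 to 107.8 ± 13.8, and Car3 (-7.95 ± 0.13), Cyp2c11 (-6.13 ± 0.09), Nrep, a protein of regenerating neurons (-5.06 ± 0.07), and Ces1d, a carboxylesterase (-4.57 ± 0.08), also fell. The other probe sets of Abcb1 gave 2.38 and 2.03. Immune lists were shifted down, with falls in 8 of 16 lymphocyte markers (adjusted p = 1.12e-05), 5 of 7 MHC class II genes (median -1.51, adjusted p = 1.39e-06), 10 of 24 chemokine and adhesion genes with 2 rises (adjusted p = 4.66e-05), and 4 of 18 macrophage markers with 1 rise (adjusted p = 6.7e-07). Prf1 (-2.11), Cd74 (-1.48), Cxcl1 (-2.77) and Aif1 (-1.54) were among them. Red cell and granulocyte markers fell beside them, 6 of 7 (median -2.19, adjusted p = 1.09e-07), and so did 2 of 16 endothelial markers (Plvap, -2.52, and Lyve1, -1.29; adjusted p = 0.000149) and 4 of 28 matrix genes (Lum, -3.02, and Col1a1, -1.26; adjusted p = 1.12e-05).

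Metabolism also shifted between 3 and 6 weeks. Fatty acid synthesis had 8 falls and 1 rise in 17 (median -0.91, adjusted p = 4.12e-07), with Scd, a desaturase, falling by 2.30 and Fasn by 2.18. Cell cycle genes had 9 rises in 35 (adjusted p = 0.000214) and stress genes 10 in 24 (adjusted p = 0.000118), among them Cdkn3 (2.07), Rrm2 (1.69) and Herpud1 (1.59). In the lists of P450 genes (3 rises and 4 falls in 25, adjusted p = 0.000118), plasma proteins (3 falls in 27, adjusted p = 2.83e-10) and fatty acid oxidation (4 rises and 1 fall in 21, adjusted p = 0.00205), the test passed at the preset correlation. With an estimated correlation their adjusted p was 0.145, 0.154 and 0.173. Cholesterol synthesis had 1 fall (adjusted p = 0.000247; adjusted p = 0.0512 with an estimated correlation). Acute phase genes had 2 rises and 2 falls in 20 (adjusted p = 0.000286; adjusted p = 0.154 with an estimated correlation; 0.0831 with quantile normalization). Phase II genes had 5 rises and 2 falls in 27 (median -0.34, adjusted p = 0.0238; adjusted p = 0.173 with an estimated correlation; 0.137 with quantile normalization). The other 6 lists did not pass.

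The step from 6 to 9 weeks asked what changed late; 200 genes rose and 61 fell. With locus and clone names left out, the largest rises included immune genes. Cxcl9 rose by 3.53 ± 0.09, from 246.4 ± 9.5 to 3018 ± 21.5, Gbp2, an interferon-induced GTPase, by 3.26 ± 0.08, Fam111a, a protease linked to DNA replication, by 3.23 ± 0.15, RT1-Ba by 2.76 ± 0.06 and Gzmm, a granzyme, by 2.64 ± 0.26. The other probe sets of RT1-Ba gave 1.91 and 0.34. Lcn2 fell by 4.13 ± 0.07, from 7795 ± 84.8 to 431.9 ± 39.5, Fst by 2.80 ± 0.28, the neutrophil defensin RatNP-3b by 2.45 ± 0.22, Defa5 by 2.13 ± 0.26 and Lratd2 by 2.05 ± 0.26. Of 7 MHC class II genes 6 rose (median 2.09, adjusted p = 2.89e-13), of 16 lymphocyte markers 7 rose (median 0.95, adjusted p = 1.28e-07), of 24 chemokine and adhesion genes 4 rose (adjusted p = 8.51e-11) and of 18 macrophage markers 3 rose (adjusted p = 1.02e-16), none with a fall. Cd3d, of the T cell receptor complex, rose by 2.54, Prf1 by 2.37, Ccl5 by 2.26 and Tyrobp by 1.39. Beside them Hbb rose by 1.37, Hba-a2 by 1.33 and Alas2, of haem synthesis, by 1.10, while Slc4a1 fell by 1.05 and Ahsp stayed at -0.06; the median of that list of 7 was -0.06, its mean 0.15 and its test direction up (adjusted p = 0.758).

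Bile duct markers rose from 6 to 9 weeks, 4 of 14 (Cd24 by 1.64 and Krt19, a duct keratin, by 1.52), with Spp1 falling by 1.39 (adjusted p = 0.000357). Plvap rose by 2.34 in the endothelial list (adjusted p = 0.00114), Vim, an intermediate filament, by 1.17 in the stellate list (adjusted p = 0.00877), and Sqle and Msmo1 by 1.31 and 1.13 in cholesterol synthesis (adjusted p = 1.53e-08). Akr1b8 and Gstp1 rose by 2.45 and 1.57 in the phase II list (adjusted p = 0.00114; adjusted p = 0.0767 with an estimated correlation). Matrix genes (Mfap4 rose by 1.03, adjusted p = 0.0181), plasma proteins (no call, adjusted p = 0.00242), urea cycle and amino acid genes (Sds fell by 1.26, adjusted p = 9.84e-07) and fatty acid oxidation genes (Pdk4 fell by 1.42, adjusted p = 0.00502) passed at the preset correlation. Their adjusted p was 0.0505, 0.51, 0.087 and 0.242 with an estimated correlation. The median of the acute phase list was 0.04 and its mean -0.14, and that of the neighbouring tissue list -0.03 and its mean 0.09; neither passed (adjusted p = 0.32 and 0.379). The beta-actin 3' to 5' ratio was 2.54 ± 0.08 at 6 weeks and 3.54 ± 0.28 at 9 weeks. That of the added thr spike was 2.05 ± 0.05 and 3.64 ± 0.19, so processing differed across this step as well.

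Over the whole course 1464 genes changed by limma's F test with at least 1 change of 2-fold. Spink1, Abcc3 and Tgfb1 were among 122 genes higher at all 3 times, and A1bg, Obp3 and Cpa1 among 67 lower at all 3. The largest pattern, 291 genes, was a rise at 6 and 9 weeks without a call at 3 weeks, as for Acot1; 184 genes fell at 6 weeks alone, and 180 fell at 6 and 9 weeks, as did Car3 and Cyp2c11. Genes higher at both of 2 times numbered 139 for 3 and 6 weeks, 179 for 3 and 9 weeks and 413 for 6 and 9 weeks, where independent lists of the same sizes would share 15.5, 19 and 33.5. Genes lower at both numbered 76, 74 and 251, against 5.8, 4.8 and 16.6. The changes correlated across genes at r = 0.533, 0.61 and 0.848 with covariances of 0.181, 0.204 and 0.403. Simulated groups without change were drawn with the spread between arrays and tested against 1 shared simulated 0h group. They gave r = 0.502, 0.5 and 0.501 with covariances of 0.0124, 0.0123 and 0.0124, and at most 1 shared call. That spread leaves little room for 2-fold calls, and differences between animals at 0h were not simulated. Part of the excess may come from the shared 0h arrays.

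Some genes changed in opposite directions. Against 0h, 24 genes were higher at 1 time and lower at another: A2m, Fasn, Mx1 and Slpi rose at 3 weeks and fell at 6 weeks, Cxcl9 and Psmb9 were lower at 6 weeks and higher at 9 weeks, and S100a9 and Hdc, histidine decarboxylase, were higher at 3 weeks and lower at 9 weeks. The difference between the times was itself called in each pair (17 genes for 3 and 6 weeks, 5 for 6 and 9 weeks, 8 for 3 and 9 weeks). That follows from opposite 2-fold calls against the same 0h arrays and is no separate evidence. From 3 to 6 weeks and on to 9 weeks, 126 genes fell and then rose, among them Cd74, Prf1 and Plvap, and 14 rose and then fell, among them Lcn2, Spp1, Pdk4 and Sds.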

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

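The tests of fewer hepatocytes, of less blood at 6 weeks, of more blood at 9 weeks, of the female-biased genes with those left out put back and of the clock genes without Nfil3 and Cry1 were chosen after the results were seen, as were the male-biased, female-biased, interferon-induced and erythroid lists. The MHC class II medians and the counts of genes that moved in opposite directions stood out because the times differed, and the control probe sets and the probe sets with no single gene name because they lie outside the gene comparisons and carried signals that differed from 0h. The male-biased and clock genes met neither condition and are weighed because their changes were noticed in the data.

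Male-biased liver genes fell: of 12 measured, 7 fell and 1 rose at 6 weeks (median -3.10), and 6 fell and 1 rose at 9 weeks (median -2.27), with Cyp2c11, Car3, Ces1d and Obp3 falling and Cyp2c13, Slco1a1 and Hsd11b1 not called. Fewer hepatocytes would lower their other abundant transcripts as well, but the median of plasma and coagulation proteins changed by -0.512 at 6 weeks, far less than that fall. The male-biased list holds the falls that prompted it, and 4 of 27 plasma proteins fell at 6 weeks and none rose. The comparison therefore bears only on fewer hepatocytes as the whole source, and a part is not excluded. A turn from a male to a female pattern would raise female-biased genes as a set. Of 11 at 6 weeks against 0h, 3 fell and Cyp17a1 rose, by 3.47 (median -0.86, adjusted p = 0.00441, and 0.18 with an estimated correlation). A1bg, Akr1b7 and Srd5a1 had been left out because already seen. With them put back, the median of 14 was -0.90, with a 95% interval over genes of -3.30 to 0.34, below the 0.5 set for a turn. Cyp2c12, a female-specific P450, was already bright at 0h, at 33977 ± 2338, which leaves less room for a rise from there. A1bg, among those put back, was bright at 0h too, at 25852 ± 1396. From 3 to 6 weeks, when Cyp2c11 and Car3 fell, the 11 genes had 2 rises and 1 fall (median 0.142, adjusted p = 0.644). The values from 0h therefore cannot decide on a turn, because such female-biased genes were bright there. No bound was set for the later step. A different sex makeup of the animals may contribute and stays open, because the labels do not give the sex and the only measured Y-linked gene, Uty, changed by -0.514 at 6 weeks, between what a change of sex and no change would give, and a biological effect of carbon tetrachloride on male-biased genes is open as a hypothesis.

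MHC class II genes and lymphocyte markers were lower at 6 weeks than at 3 and 9 weeks: the median of the MHC class II list changed by -1.514 from 3 to 6 weeks and by 2.086 from 6 to 9 weeks. The scaling of the arrays is argued against, since with quantile normalization the lymphocyte markers still had a median of -0.967 from 3 to 6 weeks. Less blood in the 6 week samples stays open: the median of the erythroid genes changed by 1.101 from 6 to 9 weeks, beside 0.954 for lymphocyte markers, but Ahsp and Slc4a1 did not rise and the falls of these genes at 6 weeks had been seen, so they cannot support it. For the MHC class II genes at 9 weeks, more blood than at 0h is argued against, since the erythroid median was -1.075 against 0h. An interferon response that differed between the groups is consistent with a median of 0.909 in interferon-induced genes from 6 to 9 weeks and remains a hypothesis.

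Clock genes differed between the groups. Nr1d1, a clock repressor, changed by -2.38 at 3 weeks, -2.13 at 6 weeks and 0.14 at 9 weeks, and Dbp by -1.50, -1.92 and -0.23. Tissue taken at different times of day could be a source, and would move activators and repressors apart. Their medians were 0.266, 0.219 and 0.957 apart at 3, 6 and 9 weeks, between the bounds set for and against it, but the 4 listed activators included the repressors Nfil3 and Cry1, and with these left out, which leaves 2 genes, the largest gap was 1.397. Nr1d1 is not in the repressor list, whose 7 measured genes had 1 rise and 2 falls at 3 weeks, so the list median can hide a shift. The outcome depends on the list and the labels do not give the time of day. Tissue taken at different times of day therefore cannot be told apart from an effect of the model.

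Over all genes tested, 126 fell from 3 to 6 weeks and rose from 6 to 9 weeks, Car3 and A2m among them, and they were not tested for any class of gene. The second kept probe set of Car3 gave 0.36 from 6 to 9 weeks, short of 2-fold. A rise at 1 time and a fall at another was found in 24 genes, and the call of the difference between the times follows from it. The added poly-A spikes were brighter at 3 weeks than at 0h by 1.129 log2 units in the mean (2386 ± 57.4 against 1094 ± 102). Whether this bears on the calls at 3 weeks was not tested. The 5S rRNA control probe set had a signal of 1236 ± 52.6 at 6 weeks and 343.4 ± 22 at 0h. Of 4822 kept probe sets with no single gene name, 384 were called at 6 weeks. Beside them 988 of the 10321 named genes were called, so the unnamed probe sets were not called more often.

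Other splits of the 6 arrays compared were counted for each comparison. The real split called 425 genes for 3 weeks, 989 for 6 weeks, 1025 for 9 weeks, 777 for 6 against 3 weeks and 257 for 9 against 6 weeks, and the highest of the other splits called 0 in each. The real split was the only 1 of 10 with as many genes, and 10 splits are too few for a share under 0.05. For the time course, 1 of 100 groupings of the 12 arrays, the real one, called as many genes, 1464, and the highest other called 990, a share under 0.05. The labels call the arrays of a group technical replicates, so this excludes chance only in how arrays were grouped, and chance differences between animals are not excluded.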

How the results depend on the processing

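Leaving out whole times, the overlap and dip counts under settings not planned for them, and all settings for the dip count were chosen after seeing the data. No list call or named gene reversed, but the balance of rises and falls did in places: from 3 to 6 weeks there were 399 rises and 386 falls with median centring (the cause was not tested) and 2713 and 2337 with no fold minimum, and at 6 weeks 157 and 164 with at least 3-fold. The total counts were within 1.5 times those reported with a pseudocount of 1, no filter, quantile normalization, median centring, the mean of probe sets, eBayes without the trend, adjusted p under 0.01 and the other deposited table. With no filter, which tests more genes, falls alone exceeded this, at 226 against 132 at 3 weeks and 93 against 61 from 6 to 9 weeks. With a pseudocount of 64, which shrinks the change of dim genes, 286 genes were called at 3 weeks and 166 from 6 to 9 weeks, and 63 were higher at all 3 times. With the filter at the 60th percentile, which tests fewer genes, 282 were called at 3 weeks 76 were higher at all 3, and 34 fell from 6 to 9 weeks.

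With every probe set tested, named or not, the counts were 822, 1657 and 1887 at 3, 6 and 9 weeks, 1254 from 3 to 6 and 508 from 6 to 9 weeks, 2686 over the course, 226 higher and 109 lower at all 3 times, and 191 that dipped at 6 weeks; more features are tested there. With no fold minimum they were 4381, 5616, 5744, 5050, 2674, 7404, 1271, 950 and 919, and with at least 3-fold 102, 321, 315, 240, 69, 465, 27, 23 and 38, in the same order; the threshold itself moves these.

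Leaving out 1 array gave 443 to 460, 991 to 1011, 1028 to 1046, 777 to 804, 254 to 275, 1460 to 1510, 115 to 137, 62 to 69 and 123 to 135. Without all arrays of 3, 6 or 9 weeks the course had 1333, 1191 or 1175 genes. The replicate numbers do not pair the samples: residuals of arrays with the same number correlated at r = -0.04 to 0.124 over 18 pairs, 2 of them over 0.1. With the number as a block the counts were 434, 985, 1025, 777 and 261, and 1462 over the course.

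Of 110 list tests, 29 passed only at the preset and not at the estimated correlation, and fry called 29 more. Quantile normalization ended 5 list calls and made 3. Named genes near 2-fold (Mmp19, Plk1 and Ramp2 with a pseudocount of 64, Mmp19, Fads2 and Ramp2 with quantile normalization, Mmp19 with median centring) fell short of it, as did Onecut1 at 3 weeks with the mean of its probe sets (-0.89), whose probe sets differ. The cause was not tested for the others. Signals below 75.3 limit the changes of dim genes.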

Other observations

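The lists described here were written once the data were in hand: the interferon, erythroid, amino acid response, endoplasmic reticulum and sex-biased lists after the largest changes had been seen, and the clock, Y-linked, ribosomal and mitochondrial lists before their own values were seen. Of 22 interferon-induced genes measured, Mx1 and Mx2, antiviral GTPases, rose at 3 weeks (median 0.42, adjusted p = 3.15e-07), 4 fell and Oasl rose at 6 weeks (median -0.40, adjusted p = 0.000152), and Oasl, Rsad2 and Isg15 rose at 9 weeks, by 2.40, 1.72 and 1.26 (adjusted p = 0.00604; adjusted p = 0.0674 with an estimated correlation). From 3 to 6 weeks 10 fell and from 6 to 9 weeks 11 rose, among them Psmb8, of the immunoproteasome, by 1.72 (adjusted p = 3.72e-18). Erythroid genes had 4 falls of 5 at 6 weeks (median -2.13) and 3 at 9 weeks (median -1.08), and their median at 3 weeks was -0.12 with a mean of 0.09.

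Amino acid response genes, targets of the transcription factor ATF4, rose at 6 weeks, 6 of 19 (median 0.76, adjusted p = 1.46e-05), and at 9 weeks, 5 of 19 (median 0.71, adjusted p = 7.01e-05), with none called at 3 weeks. Asns, asparagine synthetase, rose by 2.24 at 6 weeks, Atf5 by 1.79, Slc7a11, the cystine carrier, by 1.38 and Slc3a2 by 1.33. Of the genes of protein folding and secretion, 4 of 20 rose: Hyou1, a chaperone of the endoplasmic reticulum, by 2.59, Ssr3 by 1.34, Dnajb9 by 1.31 and Sec61a1, of the translocon, by 1.26 at 6 weeks (adjusted p = 1.43e-08). At 9 weeks 3 of the 20 rose (adjusted p = 0.00344, and 0.137 with an estimated correlation). This list is not among those that leave out genes already seen, so its p-values are not independent tests. None of 36 cytosolic ribosomal protein genes was called at any time; their median was 0.26 at 6 weeks (adjusted p = 1.75e-06; adjusted p = 0.213 with an estimated correlation). None of 28 mitochondrial respiratory chain genes was called either, with a median of -0.28 at 9 weeks (adjusted p = 5.13e-06).

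Among male-biased genes, Cyp4b1 was the one that rose, by 1.59 at 6 weeks and 1.94 at 9 weeks; the list holds the falls that prompted it, so its test is not given. Of 11 female-biased genes, Prlr, the prolactin receptor, fell by 1.58 at 3 weeks, 2.66 at 6 weeks and 2.86 at 9 weeks, and Trim24 by 1.84, 1.49 and 1.25, while Cyp17a1, of steroid synthesis, rose by 1.42, 3.47 and 3.25. At 6 weeks that list had adjusted p = 0.00441, and adjusted p = 0.18 with an estimated correlation. The alpha-2u globulin paralogs LOC259246 and LOC259245 moved with Obp3, by -8.32 and -6.92 at 6 weeks. The Y-linked gene Uty was not called at any time (-0.34, -0.51 and -0.65). Of the 4 measured genes listed with the clock activators and not tested, Npas2 was lower at 6 and 9 weeks, by -1.61 and -1.34, and Nfil3, which is a repressor, was higher at 6 weeks, by 1.22. Among 7 clock repressors and outputs, Nr1d2 (-1.16) and Dbp (-1.50) fell at 3 weeks and Dbp (-1.92) at 6 weeks, while Per2 rose by 1.86 at 3 weeks, Bhlhe41 by 1.31 at 6 weeks and 2.01 at 9 weeks, and Usp2 by 1.72 and 1.26 (adjusted p = 0.949, 0.585 and 0.212 at 3, 6 and 9 weeks).

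Probe sets with no single gene name were called in numbers of 225, 384 and 408 of 4822 at 3, 6 and 9 weeks, 263 from 3 to 6 weeks and 82 from 6 to 9 weeks. Of the 10321 named genes, 433, 988, 1027, 776 and 261 were called in the same comparisons. The hybridisation spikes had a mean signal of 3659 ± 561 at 0h and 3000 ± 44.2, 2290 ± 54.5 and 3013 ± 13.6 at 3, 6 and 9 weeks. The poly-A spikes had 2309 ± 53.9 at 6 weeks and 1494 ± 18.3 at 9 weeks. The 3' to 5' ratio of the dap spike was 1.36 ± 0.04 at 0h, 1.34 ± 0.04 at 3 weeks, 1.40 ± 0.01 at 6 weeks and 2.53 ± 0.11 at 9 weeks.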
